A study of Homo sapiens with 2 samples.

How the data were processed

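RNA was measured in spheroids of MDA-MB-231, a human triple-negative breast cancer cell line kept in medium with 10% serum. Per the labels, 1 spheroid sample was left as Control and 1 was treated with TGS24, a compound known here by its code name only. Its dose and the length of treatment are not given in the sources used here. Total RNA was extracted with Trizol and sequenced as 150-bp paired-end reads, per the labels' protocols. The groups were taken from the sample titles, and each held 1 library.

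The submitters' processing notes name Trimmomatic, Bowtie2 2.2.4, STAR, featureCounts 1.5.2, DESeq2 and the genome build hg19, without the role or order of any tool. Strand handling, treatment of multi-mapping reads and the annotation release are not given in the sources used here. The reference at hand was GENCODE v29 on GRCh38, so no coordinates are printed, and it served only for GC content, transcript sequences and exon overlaps by Ensembl identifier.

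The authors deposited 3 tables with a value per gene and library: all genes (57773 rows), genes with a value above 0 in both libraries (17133 rows), and called genes (900 rows). These deposited values are a normalized signal, gene read counts divided by 1 size factor per library, as read from the steps between the values. A read was worth 0.969 in the Control column and 0.506 in the TGS24 column, that is, size factors of 1.03 and 1.98. Dividing by these steps gave whole reads, within a relative tolerance of 1e-06, for 99.98% of Control values and 99.98% of TGS24 values. Among genes with reads, 75.3% of Control counts and 73.5% of TGS24 counts were even, as when both mates of a pair are counted. Intervals were therefore computed on read pairs. In the filtered and called tables the deposited ratio (fold change) is TGS24 over Control without a pseudocount, and the deposited log2 value is its logarithm, by the authors. In 6 called rows the deposited log2 value was not that of the row's own values, as for VIM, at -0.69 against -2.11. Lines without a gene (9) close the filtered table and hold the authors' mean and SD of the log2 values. The design fixed beforehand assumed counts and p-values in the tables, which hold normalized values, ratios and calls.

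The authors' size factors stand in a ratio of 1.92, and median-of-ratios factors computed here over all genes stand in a ratio of 1.75. In 29 rows the gene symbol had turned into a date, and these rows kept their Ensembl identifiers. In the table of all genes 49 rows were irregular. These rows repeated an identifier, stood out of identifier order, were not whole reads, or held other values in the filtered or called table. They were left out, with 0.676% of Control reads and 0.619% of TGS24 reads. MAPK12 is among them, and its values are given from each table by name.

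For the comparison, recovered reads were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. The log2 ratio of TGS24 over Control used scaled counts with a prior count of 2, scaled to library size, among 10080 genes with at least 20 reads over the 2 libraries. A 95% Clopper-Pearson interval, conditional on the total of read pairs, accompanies each ratio. It covers counting error only. A gene was counted as at least 2-fold higher or lower when its log2 ratio was at least 1 in size and its interval left out 0. With 1 library per group there is no replicate check, no p-value across genes is given, and each statement compares these libraries, not the conditions. Calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

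Gene lists (39) and the rule for named genes were written before the data were examined. The rule took MAPK12, up to 4 members of each list with the largest log2 ratios in size, and the 12 highest and 12 lowest genes overall. Overall ranks followed the interval bound nearest 0 among genes with at least 100 reads, without unnamed loci, small RNAs, pseudogenes, antisense genes and sex-linked control genes. Other members that passed the 2-fold threshold, and genes whose rows were left out, are named outside this rule, after their values were seen. Single values of some list members are not reported here. Each list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 classes. A list stood apart under a percentile of 0.5 or over 99.5, and needed at least 3 measured members.

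The steps were tested on simulated data with the real genes' mean rates and library sizes. Of 50 genes simulated 3-fold higher 96.0% were called, and of 50 simulated 3-fold lower all were called. Among 9380 simulated unchanged genes 1.36% were called in either direction. The changed genes were drawn among protein-coding genes with at least 100 reads, and the draws held counting error alone, without a trend with GC content. These shares thus do not cover changed genes under 100 reads, or spread between libraries beyond counting error. A further simulation drew 100 pairs of libraries that differed by counting error alone and applied the authors' bounds to them.

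Alternatives covered DESeq2 1.42.0 median-of-ratios factors, library totals alone, prior counts of 0.5 and 8, other read minimums, fold thresholds of 1.5 and 4, protein-coding genes alone, and totals without small and mitochondrial RNA genes. Chosen after seeing the data were centring within 20 classes of GC content, random lists matched on GC, intervals from single reads, an exact binomial test of read pairs, all deposited rows, the other MAPK12 rows, and the authors' calls whose counting interval left out no difference.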

Results

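The series measured gene expression in MDA-MB-231 spheroids, 1 Control library and 1 library after treatment with TGS24. The table of all genes held 8570621 reads for Control and 16145093 for TGS24, in 19040 and 21945 genes with a read. Pairs of read counts are in the order Control, TGS24. RN7SL1, the RNA of the signal recognition particle, took 41.1% of the Control reads and 31.6% of the TGS24 reads. RN7SK, a small nuclear RNA that restrains transcription elongation, took 13.9% and 10.4%. Protein-coding genes held 41.3% of the reads in Control and 54.1% in TGS24. The 13 mitochondrial messenger RNAs together had 7 reads in Control and 8 in TGS24.

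The series design names the expression of MAPK12 pathway genes under TGS24. MAPK12 (ENSG00000188130) encodes p38 gamma, a stress-activated MAP kinase, and had 4 reads in Control and 10 in TGS24 in the table of all genes. This gave a log2 ratio of 0.29 with an interval from -2.23 to 3.77, so no difference was detectable at this depth. With 4 Control reads, the interval would have left out 0 only from 33 TGS24 reads upward, a 4.28-fold difference. The deposited tables do not hold a single value for this gene. In the authors' deposited table of called genes MAPK12 stands as lower in TGS24, with normalized values of 6.78 and 1.52 and a log2 ratio of -2.16. These correspond to 7 and 3 reads and to a log2 ratio of -1.52 on the scale used here, with an interval from -6.39 to 0.97. The authors' deposited table of filtered genes lists MAPK12 in 2 rows, at 3.88 and 5.06 and at 7.75 and 2.02, the latter with a log2 ratio of -1.44 on the scale used here. The direction of the MAPK12 ratio thus depends on the table, and every interval held 0.

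**Figure D1:**
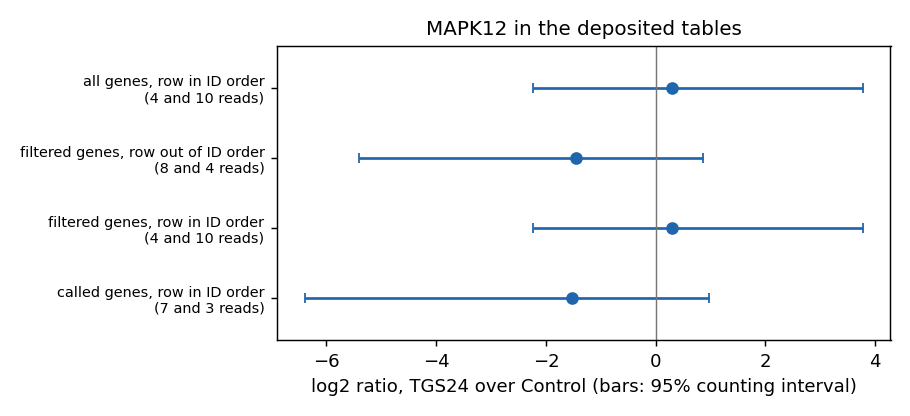
Log2 ratio of TGS24 over Control (horizontal axis) for each MAPK12 row of the 3 deposited tables, with bars for the 95% counting interval and the reads of Control and TGS24 in brackets. Points lie on either side of 0, from -1.52 to 0.29, and each bar crosses 0.

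Around MAPK12, 2 of the kinases that feed the stress-activated MAP kinases were at least 2-fold higher in TGS24. MAP3K7 (TAK1), an activator of p38 and JNK signalling, was 2.46-fold higher, on 600 and 2852 reads, and MAP3K5 (ASK1) was 2.16-fold higher, on 45 and 190 reads, with a log2 ratio of 0.95 when scaled over genes with at least 100 reads. Neither measured kinase that phosphorylates p38 passed the 2-fold threshold with the filter on low counts. MAP2K4 had a log2 ratio of 0.95, or 1.11 without that filter, and MAP2K3 one of -0.71. Centred within GC classes these were 0.41 and -0.28, the latter with an interval from -0.60 to 0.02. MAP2K6 had 0 and 3 reads. MAPK14, the p38 alpha gene, had a log2 ratio of -0.59 with an interval from -0.97 to -0.22. MAPK11 had 0 and 2 reads. MAPK13, another p38 gene, was left out like MAPK12, as the deposited tables disagree on it. In the authors' deposited table of called genes MAPK13 stands as lower, with a log2 ratio of -2.35. Its values in the authors' deposited table of all genes, 5.81 and 4.05, give -0.52. Of the 12 measured members of the p38 family and its activating kinases, 2 were at least 2-fold higher, 10 passed in neither direction, and the list median was 0.21, at percentile 61.3 of the random lists.

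Among substrates and downstream factors of p38, DLG4 was 5.85-fold lower in TGS24, on 116 and 36 reads. DLG4 encodes the scaffold protein PSD-95. Another scaffold of that family, DLG1, was 2.52-fold higher. The transcription factor ATF2 was 4.02-fold higher, on 244 and 1898 reads, and MEF2A was 2.26-fold higher. CREB1, another transcription factor, was 2.09-fold higher, and the phosphatase gene PTPN3 was 2.11-fold higher, on 16 and 68 reads. The PTPN3 interval ran from 0.004 to 2.46, and its log2 ratio was 0.93 with a prior count of 8. Without small and mitochondrial RNA genes the PTPN3 interval held 0. When scaled over genes with at least 100 reads, CREB1 had a log2 ratio of 0.90. MAPKAPK3, a kinase activated by p38, was 2.13-fold lower. Of the 17 measured members 5 were higher and 2 lower, with a list median of 0.14 at percentile 62.7.

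The JNK genes MAPK8 and MAPK9 had log2 ratios of 1.54 and 1.58, and MAPK6, which encodes the atypical kinase ERK3, was 2.46-fold higher. MAPK3, the ERK1 gene, had a log2 ratio of -0.59, not past the threshold. Of the 14 measured members of this list 3 were higher and none lower, with a list median of 0.04 at percentile 39.3. DUSP6, a phosphatase induced by ERK signalling, was 2.03-fold lower and was the single one of 13 measured ERK feedback targets past the threshold. Their median was -0.45, at percentile 4.62. Several of these kinases have AT-rich transcripts, and after centring within GC classes MAP3K7 stood at 0.59, MAPK8 at 0.75, MAPK6 at 0.51, MEF2A at 0.59, DLG1 at 0.62, CREB1 at 0.22, PTPN3 at 0.95 and MAPKAPK3 at -0.67, no longer 2-fold. ATF2 at 1.16, MAPK9 at 1.35, MAP3K5 at 1.02, DLG4 at -2.24 and DUSP6 at -1.03 stayed past the threshold. DUSP6 was under it with library totals alone, at -0.99, and with no filter on low counts, at -0.86.

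Over all 10080 genes, 1281 were at least 2-fold higher and 636 at least 2-fold lower in TGS24. The balance differed between classes of total reads. A gene higher in TGS24 has more total reads for that reason, so these classes are not independent of the ratios. Of genes with 20 to 50 reads over both libraries 71 were higher and 211 lower, with a median log2 ratio of -0.21. From 50 to 100 reads 93 were higher and 179 lower. Of genes with at least 3000 reads 270 were higher and 12 lower, with a median of 0.42. TFRC, the transferrin receptor that takes up iron, had the interval farthest above 0 and was 6.81-fold higher, on 220 and 2900 reads. ERCC6L, a DNA helicase of mitosis, was 11.3-fold higher, on 10 and 244 reads. The cohesin subunit SMC3 was 5.01-fold higher, on 555 and 5362 reads, and SUZ12, a subunit of the Polycomb repressive complex, 4.79-fold. LARP4, an RNA-binding protein, was 6.12-fold higher, the nuclear pore protein TPR 5.16-fold and the nucleolar RNA helicase DDX21 5.49-fold. The other 5 of the 12 highest genes, U2SURP, NAA15, OTUD4, USP45 and FMR1, were between 4.33-fold and 7.65-fold higher.

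At the other end, SPARC, a secreted matrix glycoprotein, was 5.08-fold lower in TGS24, on 3272 and 1239 reads. SOD2, the mitochondrial superoxide dismutase, was 5.23-fold lower, on 931 and 341 reads. KIAA1199, a hyaluronan-binding protein also called CEMIP, was 5.90-fold lower, on 215 and 68 reads. TIMP2, an inhibitor of matrix metalloproteinases, was 3.29-fold lower, the transcription factor CEBPD 3.42-fold and ANXA2, a calcium-dependent membrane-binding protein, 3.17-fold. The other members of the 12 lowest were DLG4, TINAGL1, SPRED3, WBP1, EHD2 and CCDC85B, between 3.22-fold and 5.85-fold lower. All 24 genes kept their direction and stayed at least 2-fold apart when ratios were centred within GC classes.

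**Figure D2:**
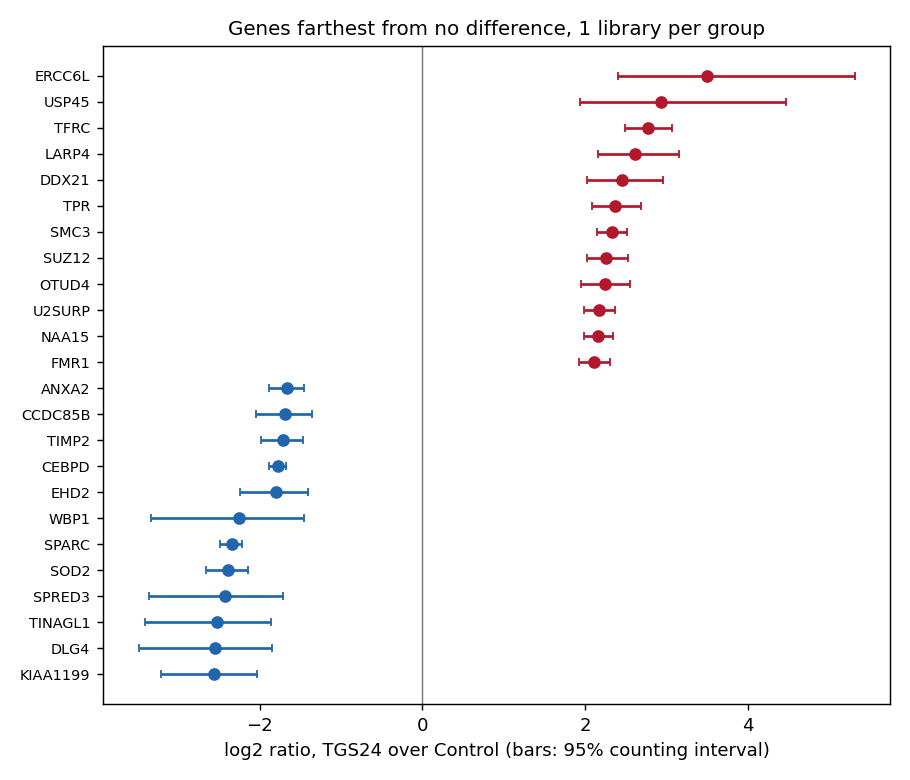
Log2 ratio of TGS24 over Control (horizontal axis) of the 12 genes highest (red) and 12 lowest (blue) in TGS24, with bars for the 95% counting interval, 1 library per group. Ratios run from -2.56 for KIAA1199 to 3.49 for ERCC6L, and no bar reaches 0.

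The log2 ratios went with GC content. The 12 highest genes had a median GC content of 38.5% and the 12 lowest one of 55.2%, against 47.4% for all tested genes. Across 5469 genes with at least 100 reads, which are not independent replicates, the log2 ratio had a Spearman rho of -0.67 and a Pearson r of -0.64 with GC content. The median ratio was 1.02 in the decile of genes lowest in GC and -0.53 in the highest decile. Higher genes made up 66.8% of all 2-fold genes. Centring within GC classes sets the median ratio of each class to 0, which by itself evens the balance, and gave 539 higher and 597 lower, 47.4% higher.

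**Figure D3:**
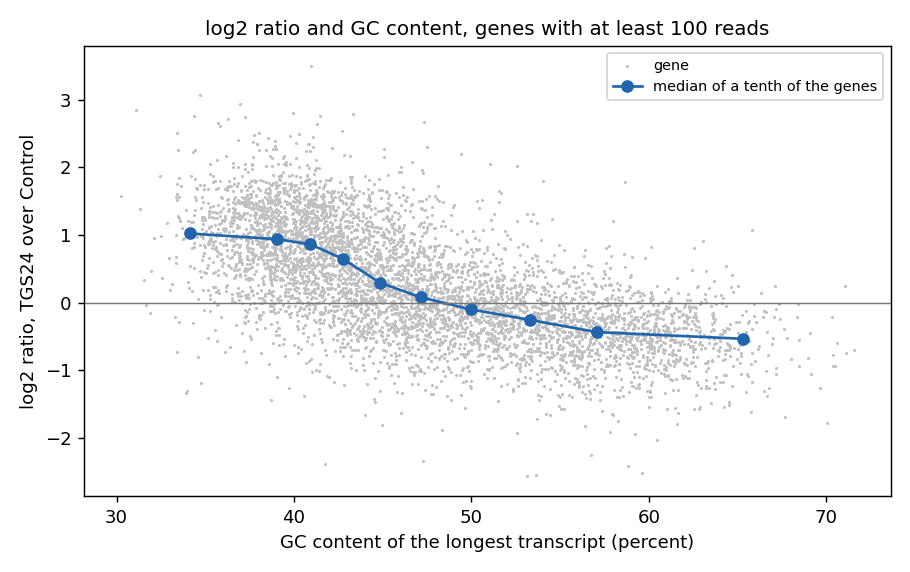
Log2 ratio of TGS24 over Control (vertical axis) against GC content of the longest transcript in percent (horizontal axis) for genes with at least 100 reads in total. Grey points are genes, and blue points are medians over deciles of the genes, which run from 1.02 at low GC to -0.53 at high GC.

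Of the 37 fixed lists with a percentile, 2 stood apart, both lower in TGS24, where lists of independently drawn genes give 0.37. Members of a list need not be independent, so 0.37 can understate what arises without any effect. Genes that mark MDA-MB-231 cells had a median log2 ratio of -1.36, below every one of the 10000 random lists. Of 8 measured members 5 were at least 2-fold lower and 3 passed in neither direction. Galectin gene LGALS1 was 4.08-fold lower, on 72 and 32 reads, ANXA2 3.17-fold, the actin-binding thymosin gene TMSB10 2.71-fold, the receptor kinase gene AXL 2.61-fold and the membrane protease gene MMP14 2.51-fold. VIM and CD44, also of this list, are among the genes on which the tables disagree. Matrix and matrix-degrading genes had a median of -0.79, at percentile 0.29. COL4A2, a basement membrane collagen, was 3.94-fold lower, TIMP2 3.29-fold and MMP14 2.51-fold, and the other 8 of 11 measured members passed in neither direction. The matrix list had a median GC content of 58.9% and no longer stood apart against random lists matched on GC, at percentile 1.22. Centred within GC classes its median was -0.38 at percentile 8.69, and without genes of more than 1 list it was -0.67 at percentile 1.07. The identity list still lay below every one of those lists. With no filter on low counts neither list stood apart, with medians of -0.15 at percentile 9.47 for the identity genes and -0.41 at percentile 1.81 for the matrix genes.

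**Figure D4:**
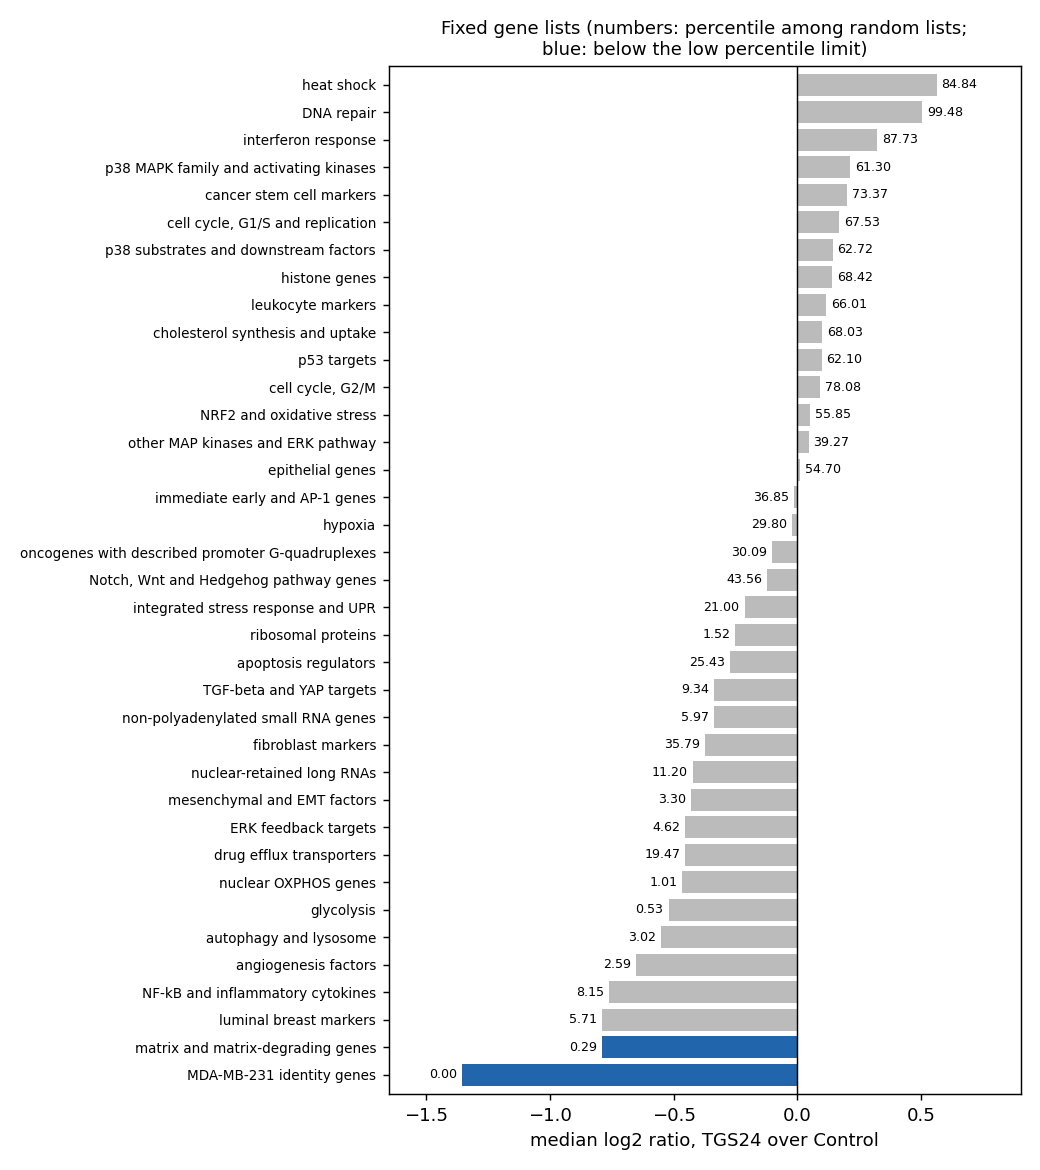
Median log2 ratio of TGS24 over Control (horizontal axis) of the 37 fixed gene lists with at least 3 measured members, with each list's percentile among 10000 random lists printed at its bar. Blue bars, the MDA-MB-231 identity genes at -1.36 and the matrix genes at -0.79, lie below percentile 0.5.

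Other lists on the state of the tumour cells had no common direction. Among mesenchymal factors SPARC was 5.08-fold lower, while N-cadherin (CDH2) was 3.17-fold higher, and the repressors SNAI2 and ZEB1 were 2.29-fold and 2.01-fold higher. Of 9 measured members 3 were higher and 1 lower, and the list median was -0.43, at percentile 3.30. SNAI2 and ZEB1, at 0.60 and 0.21, were under the threshold after GC centring. Of the 13 epithelial genes 10 were under 20 reads, and none of the 3 measured ones passed, with a median of 0.01 at percentile 54.7. Among 7 measured cancer stem cell markers the Polycomb gene BMI1 was 2.58-fold higher and no other passed, with a median of 0.20 at percentile 73.4. CD44 and SOX2 of that list are among the genes on which the tables disagree. The efflux transporter ABCC4 was 2.60-fold lower, on 40 and 28 reads, and was the single one of 6 measured transporters past the threshold. None of 14 measured Notch, Wnt and Hedgehog genes passed. The list medians were -0.45 for transporters, at percentile 19.5, and -0.12 for the pathway genes, at percentile 43.6.

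DNA repair genes leaned higher, with a median of 0.50 at percentile 99.48, just short of the limit. XRCC5, a subunit of the Ku heterodimer, was 4.32-fold higher, on 7 and 67 reads, the helicase gene BLM 3.98-fold, the checkpoint kinase gene CHEK1 3.23-fold and ATR 3.11-fold. ATM was 2.45-fold higher, and the other 13 of 18 measured members passed in neither direction. The list had a median GC content of 43.1%. Against random lists matched on GC its percentile was 93.0, and with ratios centred within GC classes it was 99.92. ATR and ATM were then at 0.98 and 0.58, under the threshold, and the interval of CHEK1 held 0. Of 8 measured heat shock genes 3 were higher, the mitochondrial chaperonin HSPD1 by 3.50-fold, on 1936 and 13064 reads, HSP90AA1 by 3.10-fold and DNAJA1 by 2.99-fold, the last at 0.99 after GC centring. The heat shock median was 0.56, at percentile 84.8. Reads shared with near-identical copies were not examined for the heat shock genes.

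Proliferation genes showed no common direction. Topoisomerase gene TOP2A was 3.08-fold higher, on 1814 and 10778 reads, and the mitotic kinase gene PLK1 was 2.32-fold lower, on 204 and 168 reads. After GC centring these stood at 0.91 and -0.86. The other 15 of 17 measured G2/M genes passed in neither direction, and their list median was 0.09, at percentile 78.1. In the G1/S list the replication clamp PCNA was 2.43-fold higher, on 18 and 88 reads, and the helicase subunit MCM4 2.19-fold, with a median of 0.17 at percentile 67.5. After centring within GC classes, with other read minimums or with a prior count of 8, ZEB1, XIAP, MDM2, SESN2, KLF6, MCM4, JUND, SRC, BMI1, COL6A3, SCARNA2, SNORD3A, RPPH1 and MMP14 each lay under the threshold, or had an interval that held 0, in at least 1 setting. Of 10 measured p53 targets MDM2 was 2.19-fold higher and SESN2 3.15-fold lower, the latter on 16 and 8 reads, with a median of 0.10 at percentile 62.1. XIAP, an inhibitor of caspases, was 2.74-fold higher and the single one of 9 measured apoptosis regulators to pass, with a median of -0.27 at percentile 25.4.

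Among immediate early genes JUND was 2.41-fold lower and KLF6 2.14-fold higher. EGR2 had 0 reads in Control and 20 in TGS24, at least 3.46-fold higher against a floor of 3 reads. That floor leaves out the counting error of the TGS24 reads, and the lower end of the counting interval on read pairs was 0.22 on the log2 scale. The median of the 12 measured members was -0.02, at percentile 36.9. Glutamate-cysteine ligase gene GCLC was 2.29-fold higher in the NRF2 list, where SOD2 was lower, and the median was 0.05 at percentile 55.9. SESN2 was the single one of 13 measured stress response genes past the threshold, and the list median was -0.21 at percentile 21.0. Of 15 oncogenes with described promoter G-quadruplexes HSP90AA1 was higher and SRC 2.40-fold lower, with a median of -0.10 at percentile 30.1.

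Of markers of other cell types, 4 of 10 for fibroblasts, 4 of 10 for leukocytes, 4 of 7 endothelial and 5 of 10 luminal ones were under 20 reads. The fibroblast collagen gene COL6A3 was lower, with a log2 ratio of -1.14, on 52 and 44 reads, and no measured leukocyte, endothelial or luminal marker passed the threshold. The list medians were -0.37 for fibroblast markers at percentile 35.8, 0.12 for leukocyte markers at percentile 66.0 and -0.79 for luminal markers at percentile 5.71. Endothelial markers had 2 measured members and mitochondrial transcripts 0, so no percentile was computed. Haemoglobin gene HBB, in the leukocyte list for blood, had 4860 reads in Control and 10453 in TGS24, and HBA2, another one, had 788 and 1502. The small non-polyadenylated RNA genes had a median of -0.34 at percentile 5.97, with RPPH1 2.32-fold lower and SCARNA2 and SNORD3A each 2.11-fold higher. Nuclear-retained long RNAs had a median of -0.42 at percentile 11.2, or 0.86 against random lists matched on GC, not under the limit of 0.5, with MEG3 4.05-fold lower, on 21 and 8 reads, and OIP5-AS1 4.04-fold higher. Without stated strand handling, OIP5-AS1 reads cannot be told from those of overlapping genes.

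Some list members short of the 2-fold threshold above passed it under other settings, as found among the members of largest ratio. After centring within GC classes the epithelial factor GRHL2 at 1.89, the mitotic kinase AURKB at 2.07 and the RNA gene RMRP at 1.31 were higher, and the apoptosis inhibitor BIRC3 at -1.78, the stress response factor XBP1 at -1.50, thioredoxin gene TXN at -1.41 and collagen gene COL1A2 at -1.32 were lower. Several of these rest on few reads, GRHL2 on 4 and 31, AURKB on 4 and 30, BIRC3 on 20 and 19 and TXN on 22 and 22. The centred interval of AURKB ran from 0.27 to 5.55. With at least 100 reads the glycolysis genes ALDOA and ENO2 were lower, at -1.15 and -1.08, and XBP1 stood at -1.06. With no filter on low counts 12 members were higher, AURKB, BCL2, CCNE2, GRHL2, HIF1A, HSP90B1, HSPH1, LYZ, MAP2K4, RMRP, SESN1 and STARD4, between 1.08 and 1.99. Of these CCNE2 had 3 and 28 reads and STARD4 had 4 and 32. Scaling factors differ in that setting, and HSPH1 moved from 0.95 to 1.11. HSP90B1 also passed with library totals alone, at 1.02. With intervals from single reads in place of read pairs 15 members passed, GRHL2 at 1.70 among them.

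The authors' own calls number 900, of which 326 are higher and 574 lower in TGS24 in the authors' deposited table. Of the 24 genes named above as highest or lowest, 19 stand in the authors' deposited table of calls, all 19 with the same direction. The 5 others, CEBPD, TIMP2, ANXA2, EHD2 and CCDC85B, have log2 ratios between -1.81 and -1.66 in the authors' deposited table of filtered genes. The bounds at the foot of the authors' deposited table of filtered genes are 2.01 and -2.15 on the log2 scale. They are given there as the mean plus and minus 2 SD, with a mean of -0.14 and an SD of 1.07. From those values the lower bound would be -2.28, which 477 filtered genes lay below, against 576 below the printed bound. Of the 900 called rows, 15 have a deposited log2 value inside the printed bounds. Of the 887 called rows with whole reads in the authors' deposited table, 546 had under 20 reads over both libraries and 92 had at least 100. The counting interval held no difference for 532 of them, 60.0%. Those with at least 100 reads were 84 higher and 8 lower, and those under 20 reads were 91 higher and 455 lower. In libraries simulated with counting error alone, a mean of 166 genes lay above the upper bound and 271 below the lower one, against 321 and 576 in the authors' deposited table of filtered genes.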

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

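All tests in this part were chosen after the irregular rows were seen. Outside the comparisons lie 49 rows of the table of all genes, left out for the irregularities given above. The deposited tables do not disagree on all of them. CTNNB1, with 6192 and 6199 in each table, was left out only because its values are not whole reads. The authors' deposited table of called genes still lists CTNNB1 as higher, at a log2 ratio of 0.0018, and DDIT4 as higher at 0.006. The 49 rows cover 38 identifiers. In the table of all genes 12 rows stand out of identifier order and 15 are not whole reads. For 6 of the 12, the authors' deposited table of filtered genes lists the same values under another gene that fits the position, such as FUCA2 where the table of all genes has PDGFB. VIM, the intermediate filament gene of mesenchymal cells, has 11398 and 7987 in the authors' deposited table of all genes, and 15.9 and 3.69 in that of called genes. CD44, a cell adhesion receptor, has 83.3 and 42.0 in the authors' deposited table of all genes and 27.1 and 3.54 in that of called genes. SOX2 has 228 and 299 in its row in identifier order and 16.5 and 6.58 in another row of the authors' deposited table of all genes, and 9.69 and 1.01 in that of called genes. Of the 38 called rows of these identifiers that have a row in identifier order in the table of all genes, 31 would lie inside the authors' bounds with the values of that row, and 7 of these 31 would have the opposite direction. The other 7 called rows would stay outside the bounds in the called direction.

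Copying errors spread over genes at random would strike the fixed lists no more often than other genes. Of 35 protein-coding genes with rows left out 16 were in the lists, 45.7%, against 514 of 17958 other protein-coding genes with a read, 2.86%. Among 10000 random draws of 35 other protein-coding genes, matched on reads in 20 classes, the most in the lists was 7 and the mean 1.30. This argues against errors at random. The draws took the place of an exact test on the same counts, which had argued the same way. A second counting of the same reads with the same size factors would give whole reads, if reads were again counted whole. Of 30 identifiers taken because their values differ between the tables of all and of called genes, 10 held a value that was not whole. This argues against such a counting as the source of the values that are not whole. For some of the 10, as TGFB1 and HSPA8, those values stand in the table of all genes and the called ones are whole. There a second counting behind the called values cannot be told apart from other steps. For the 20 with whole reads a second counting cannot be told apart from other steps, as whole reads do not show where they came from. The step that made these rows is not recorded in the sources used here, and no biological explanation was tested.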

How the results depend on the processing

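No paired analysis was possible because each group held 1 library. The alternative that adds an adjusted p to the authors' calls was not run, as the tables used here hold no p-values, and the one for FPKM, RPKM or TPM did not apply. Scaling by median-of-ratios or totals, other priors, protein-coding genes alone and totals without small RNA genes kept both 2-fold counts within 1.5 times. So did, chosen after seeing the data, single-read intervals, all deposited rows and an exact binomial test of read pairs with Benjamini-Hochberg adjustment, which compares these libraries and called 1198 higher and 526 lower genes. By construction, a threshold of 1.5-fold gave 1953 higher and 1203 lower, and 4-fold gave 156 and 85. At least 100 reads gave 874 higher and 410 lower, with fewer genes tested and TMM factors computed anew, 1.07 for TGS24 against 1.01. The new factors added lower genes. With the main factors, 147 genes of 100 to 300 reads were lower, 59 up to 1000, 28 up to 3000 and 12 beyond. Centring within GC classes, added later, gave 539 higher, as the trend was removed. The number of lists standing apart was 2, and became 4 without small and mitochondrial RNA genes, as DNA repair and glycolysis joined, 3 with library totals alone (DNA repair, percentile 99.51), 3 with all deposited rows (glycolysis, 0.495), 0 with no filter on low counts, where the median of all genes was 0.16, 1 without genes of more than 1 list, and 1 against lists matched on GC, the matrix list being lost in the last 2. Centred within GC classes it stayed 2, as DNA repair (99.92) took the place of the matrix list (8.69); the cause was not tested. The authors' 900 calls became 92 at 100 reads or more, and 355 whose counting interval left out no difference, a limit of depth. MAPK12 ran from -1.52 to 0.35 over the rows and settings tried, within the main interval. No list or named gene that passed its threshold turned direction under any alternative. For the small non-polyadenylated RNA list the GC match was void, as under 80% of members had a GC value, a rule applied after its outcome had been seen.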

Other observations

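The test of GC bias within the lists and those of shared words and overlapping exons were set before their results were seen, though the overall trend with GC and the low read counts were already known, and the other tests in this part after. These tests took the place of earlier ones on the same patterns, GC in long noncoding genes (rho -0.43 over 11 genes), pseudogenes found by name and the number of deeply read genes, after those had been seen. Glycolysis, OXPHOS and ribosomal protein genes did not stand apart. Enolase gene ENO1 was 2.02-fold lower, and the other 14 of 15 measured glycolysis genes passed in neither direction, with a median of -0.52 at percentile 0.53. The median of the 10 measured OXPHOS genes was -0.46 at percentile 1.01, and that of 20 ribosomal protein genes was -0.25 at percentile 1.52, with RPL13 2.09-fold lower and RPS6 2.03-fold higher. Against random lists matched on GC these 3 lists lay at percentiles 5.21, 2.74 and 5.62. No hypoxia or cholesterol gene passed, with medians of -0.02 at percentile 29.8 and 0.10 at percentile 68.0. Ribosomal protein and glycolysis genes have many processed pseudogenes, so their reads are uncertain. After GC centring ENO1, RPL13 and RPS6 were under the 2-fold threshold.

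Signalling targets went both ways. SKIL and SMAD7, feedback inhibitors of TGF-beta signalling, were 5.70-fold and 3.46-fold higher, while INHBA, an activin subunit, was 5.66-fold lower, on 24 and 6 reads, and THBS1, a matrix glycoprotein, 2.27-fold lower, on 13409 and 11367 reads. AXL of this list, named above, was lower too, and the other 6 of 11 measured members passed in neither direction. Their list median was -0.34 at percentile 9.34, and that of angiogenesis factors, where THBS1 alone passed, was -0.65 at percentile 2.59. Interleukin gene IL1B was 4.32-fold lower, on 18 and 6 reads, in the cytokine list, whose median was -0.76 at percentile 8.15 with 14 of 18 genes under 20 reads. No interferon response gene passed, with a median of 0.32 at percentile 87.7. In the lysosome list WIPI1 and CTSB were 2.56-fold and 2.62-fold lower and LAMP2 2.13-fold higher, CTSB and LAMP2 not past the threshold after GC centring, with a median of -0.55 at percentile 3.02. The linker histone gene HIST1H1B was 4.69-fold higher, on 8 and 82 reads, with a histone median of 0.14 at percentile 68.4.

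Genes higher in TGS24 were AT-rich. A difference in depth would fade in deeply read genes, yet rho with GC was -0.70 over 2023 genes at 1000 reads or more. This argues against depth. A candidate explanation is a GC bias that differs between the libraries, which should also act among genes of 1 pathway. Across 368 list genes, deviations from the list medians of log2 ratio and GC had a Spearman rho of -0.42, as such a bias would give. An effect of TGS24 on AT-rich transcripts would give it too, and the overall trend was already known. This value therefore favours neither explanation, and with 1 library per group they cannot be told apart.

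Several genes that MDA-MB-231 cells or human cells in general use were near 0 reads in both libraries. Of 32 identity and OXPHOS genes 14 were under 20 reads, among them S100A4 with 2 and 4 reads, PLAUR with 2 and 4, NDUFA1 with 2 and 0 and COX7C with 6 and 2, while RPLP0 had 42633 and 76653. Of the OXPHOS genes 10 of 20 were under 20 reads, and another human cell type that uses them does not account for that part of the pattern. Whether red blood cells could was not tested, and haemoglobin gene HBB had 4860 and 10453 reads. For the identity genes, 4 of 12 under 20 reads, another cell type cannot be told apart without a reference library of the line. Near-identical copies or overlapping genes could remove reads, but all 14 had under 50% of their 50-base words in other genes, at most 40.7%, and all 14 had under 50% of their exonic bases overlapped, at most 44.5%. These values argue against copies and overlaps as the whole cause, no biological explanation was tested, and the cause stays open.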
